A study of Homo sapiens with 4 samples.

How the data were processed

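Total RNA of infected HepG2 cells (24 h of plating, then 48 h of infection, 72 h in all) was converted to biotin-labelled cRNA from 6 µg and hybridised to Affymetrix GeneChip arrays, per the labels' protocols. The deposited values are on the log2 scale and were made by the authors with affy and RMA, per the submitters' processing notes; versions and settings are not given in the sources used here. RMA corrects background, makes the arrays' distributions alike by quantile normalization and summarises probes into probe sets, so a change shared by most genes would be removed and differences near background are compressed. The array medians lay between 6.63 and 6.66 and the values between 2.59 and 14.73, on 22277 probe sets per array. Values were used as deposited. Background correction could not be redone from them.

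Groups and replicate numbers came from the sample titles: 2 arrays with wild-type ATP7B and 2 with ATP7B H1069Q. All 4 arrays entered 1 fit with no replicate block. The sources used here give no scan date or batch, so batches could not be tested. After 62 control probe sets were set aside, 22215 remained, of which the platform annotation named 1 gene for 19064, several for 1043 and none for 2108. Of those with 1 gene, 19052 matched a current gene record by identifier and 0 symbols were updated. Probe sets with a mean over the 4 arrays under the 30th percentile (log2 5.27) were left out, leaving 15550, and each gene was measured by its single-gene probe set with the highest mean, which gave 9151 genes. The control probe sets entered no gene test; from them the 3' minus 5' gaps, the 18S rRNA level and the spike levels were compared between the groups.

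Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The residual degrees of freedom were 2 and the prior degrees of freedom 3.36. Gene lists with 5 or more measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 35 lists. An estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were alternatives. The lists were the p38 and JNK pathway, immediate early and ERK feedback genes, ER chaperones, ER-associated degradation, the ATF4 and CHOP response, cytosolic heat shock, metallothioneins, copper handling, NRF2 targets, proteasome subunits, cholesterol synthesis, fatty acid synthesis and oxidation, hepatocyte genes, drug and bile acid metabolism, acute phase, interferon response, NF-kB targets, p53 targets, apoptosis regulators, DNA replication, mitosis, autophagy, lysosome, ER to Golgi transport, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, core histones, TGF-beta targets, and markers of fibroblasts, endothelium, leukocytes, cholangiocytes and packaging cells. Each list was also counted gene by gene with adjustment over the list alone and over all genes. The tests, lists, naming rule and all but 2 of the alternatives were set before the data were examined.

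The naming rule took ATP7B, then the 12 largest increases and 12 largest decreases among genes past adjusted p 0.05 with no overlap of arrays, any free places going to genes with an unadjusted p under 0.01 and no overlap, and up to 4 members of each list by smallest unadjusted p. Since 0 genes passed, all 24 places were filled by the second criterion.

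The procedure was tested on simulated data for 9151 genes with this design and 200 genes changed, less any in the shifted list. At a log2 change of 0.5, 0% of changed genes were called. At 1, 85.9% of 199 were called, and at 2, 99.5% of 200. With no change there were 0 calls and 473 genes at an unadjusted p under 0.05. A list shifted by -0.3 was called by camera at the preset correlation in each of these simulations with changes (adjusted p at most 6.53e-13) and missed with an estimated correlation (adjusted p at least 0.342). The simulation gave every array the same error, which the 4 arrays do not show. It also drew errors independently between genes, so it cannot show how often a list of correlated genes is called falsely.

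Alternatives changed the filter (none, or the 50th percentile), the normalization (quantile again, or median centring), the background (50 added on the linear scale), the replicate block, the variance moderation (trend or robust), the probe sets (mean per gene, or every probe set), the threshold (0.10), the set test, and left out each array in turn. A crossed pairing and the removal of cross-hybridising probe sets were added after the data were seen. No genome coordinates are given because the sources used here name no build.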

Results

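Gene expression was measured on Affymetrix GeneChip arrays in HepG2, a human hepatocellular carcinoma cell line that is widely used as a model of the hepatocyte. The cells carried adenovirus encoding a GFP-tagged ATP7B, the copper-transporting ATPase that moves copper from the hepatocyte into bile and is mutated in Wilson disease. The virus of 1 group encoded wild-type ATP7B and served as the control, and the virus of the other encoded ATP7B H1069Q, a frequent Wilson disease variant that is retained in the endoplasmic reticulum (ER). Each group had 2 arrays, which the labels call biological replicates. Nothing further says how the cultures were separated, so the p-values measure the spread between these samples, part of which may be technical. Infection took place 24 h after plating, and cells were harvested 48 h later. After probe sets were reduced to 1 per gene, 9151 genes were tested. The number of arrays limits the precision: the median moderated standard error (SE) of a log2 difference was 0.10. Every SE given here is limma's moderated value, which draws a gene's variance toward that of all genes. For genes with a wide spread between arrays it is smaller than their SDs imply, and for genes with little spread larger. An exact two-sided permutation test of 2 against 2 arrays cannot give a p below 0.333. All differences are H1069Q minus wild type on the log2 scale, and all group values are means ± SD with n = 2.

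The 4 arrays were not equally spaced. The SD across genes of the log2 difference between arrays was 0.14 for the H1069Q pair and 0.23 for the wild-type pair. Wild-type replicate 2 lay at 0.19 and 0.23 from the H1069Q arrays, no farther than from its own replicate, whereas wild-type replicate 1 lay at 0.33 and 0.38 from them. A sign of RNA quality also differed between the groups. The 3' minus 5' gap of the actin control probe sets was 1.10 ± 0.03 in wild-type and 1.32 ± 0.09 in H1069Q arrays, and that of GAPDH was 0.26 ± 0.03 and 0.33 ± 0.04, both larger in each H1069Q array than in either wild-type array.

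The first comparison asked whether ATP7B mRNA itself differed between the groups. The ATP7B probe set read 9.14 ± 0.12 in wild-type and 8.98 ± 0.12 in H1069Q arrays, a difference of -0.16 (SE 0.11, limma adjusted p = 0.407), and the arrays of the groups overlapped. Both groups carried an ATP7B transgene, so this value bears on dose and not on the labels. Whether the probe set lies in a part of the transcript that the transgene contains is not given in the sources used here, and if it does not, the value describes the endogenous gene alone.

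The main comparison asked which genes differ when the H1069Q variant is expressed in place of the wild-type protein. Among genes with an unadjusted p under 0.01 and no overlap between the arrays of the groups, those with the largest negative differences were IL1R2, the decoy receptor for interleukin 1, HAMP, which encodes the iron hormone hepcidin, and ODAM. IL1R2 was 3.15-fold lower (7.97 ± 0.59 against 6.31 ± 0.18, difference -1.66, SE 0.28). HAMP was 2.99-fold lower (9.05 ± 0.70 against 7.47 ± 0.17, difference -1.58, SE 0.32), and ODAM 2.98-fold lower (10.91 ± 0.36 against 9.34 ± 0.25, difference -1.58, SE 0.20). Others among the 12 largest were HSD17B6, a steroid dehydrogenase, at -1.52, CPB2, a plasma carboxypeptidase that slows fibrinolysis, at -1.39, DIO1, a thyroid hormone deiodinase, at -1.36, and SERPINA6, the plasma carrier of cortisol, at -1.25. The remaining 5 of the 12 were SERPINI1 (-1.43), PSMB9 (-1.23), NDRG4 (-1.17), CORO1A (-1.15) and UNC93A (-1.15).

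By the same rule, the largest positive difference was in C5AR1, a receptor for complement C5a, which was 2.49-fold higher (5.85 ± 0.63 against 7.17 ± 0.25, difference 1.32, SE 0.30). HAL, the histidine-degrading ammonia lyase, was 2.22-fold higher (8.85 ± 0.64 in wild-type arrays, difference 1.15, SE 0.29), and the histone gene H2AC6 was 2.06-fold higher (difference 1.04, SE 0.24). The next by this rule were ITGA1 (0.97), AVEN (0.95), DRC8 (0.93), GOLM1 (0.91), OR7E14P (0.89), MTHFD2L (0.82), STS (0.81), VNN3P (0.79) and PYROXD1 (0.78). Another probe set of STS differed by only 0.19, and another of HAL by 0.55. C5AR1, ITGA1, GOLM1, MTHFD2L, STS and VNN3P had wild-type means below 6 on the log2 scale, near the lower end of the values kept.

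None of these 24 genes passed the test. With limma, 0 of 9151 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.172. At an unadjusted p under 0.05 there were 2041 genes, 890 higher and 1151 lower, where 458 would be expected if none differed. The arrays of the groups did not overlap in 57.1% of genes, against 33.3% by chance. Wild-type replicate 1 was farther than replicate 2 from the H1069Q mean in 23 of the 24, against 68.9% of all genes. Without wild-type replicate 1, the differences of the higher genes ranged from 0.51 to 0.93 and those of the lower genes from -0.81 to -1.32. Without wild-type replicate 2, 1647 genes passed, 838 higher and 809 lower, under the assumption that the lone wild-type array varies like the H1069Q pair.

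**Figure D1:**
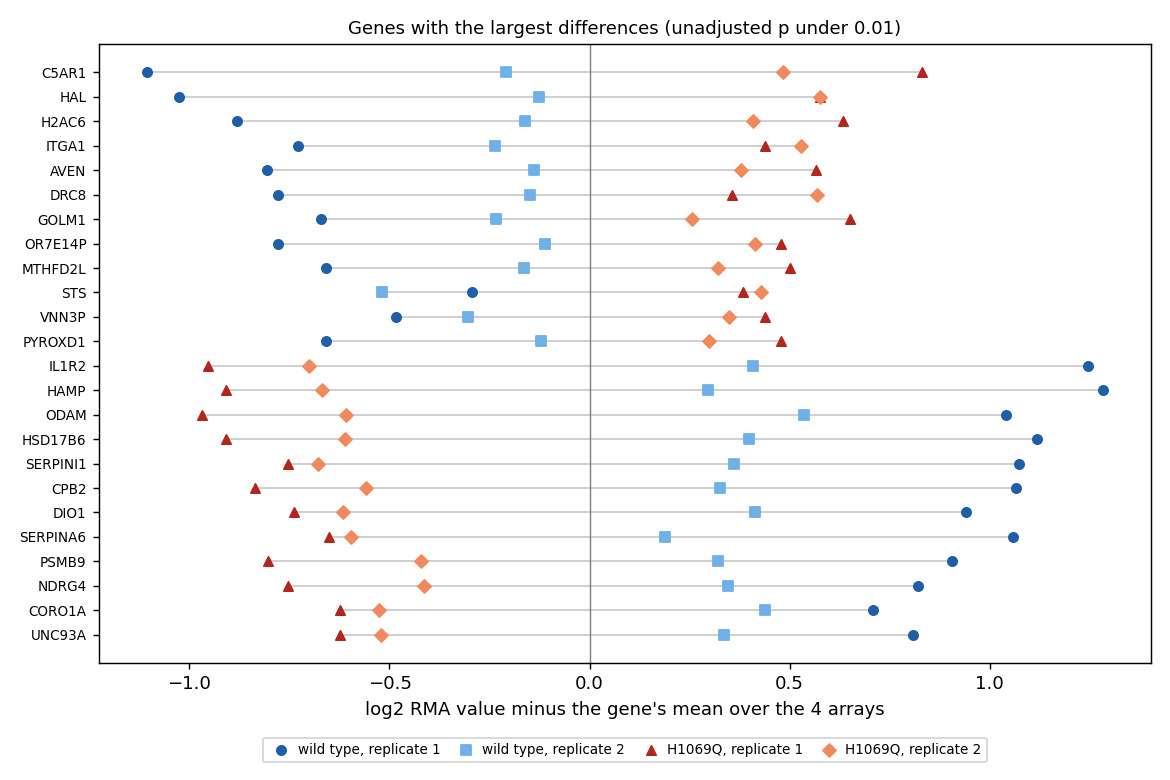
Log2 RMA value of each array minus the gene's mean over the 4 arrays (horizontal axis) for the 12 genes with the largest increase and the 12 with the largest decrease among those with an unadjusted p under 0.01, none of which passed adjustment. Each symbol is 1 array and lines span the range; both H1069Q arrays lie to one side of both wild-type arrays, and wild-type replicate 1 is the farther wild-type array in 23 of the 24 genes.

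The next comparison asked which of 35 gene lists shifted as groups. Genes of DNA replication were lower in H1069Q cells: 29 of the 30 measured members had negative differences, with a median of -0.43, and the list fell in the camera test with the preset correlation (adjusted p = 4.26e-09). This call was lost in camera with an estimated correlation (unadjusted p = 0.148, adjusted p = 0.839). That adjusted value was shared by most lists, so it does not rank them. The replication initiation factor MCM10 read 8.33 ± 0.04 in wild-type and 7.68 ± 0.09 in H1069Q arrays (-0.65, SE 0.09). POLE2, a subunit of DNA polymerase epsilon, differed by -0.75 (SE 0.14), RRM1, a subunit of ribonucleotide reductase, by -0.51 (SE 0.09), and CDC45, part of the replicative helicase, by -0.45 (SE 0.09). At an unadjusted p under 0.05, 19 members were lower and 1 was higher. Adjusted over the list alone 18 were lower, and over all genes 0.

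Genes of mitosis were also lower, with negative differences in 31 of 32 members and a median of -0.20, and this list fell as well (camera adjusted p = 6.04e-07). Here too the call was lost in camera with an estimated correlation (unadjusted p = 0.112, adjusted p = 0.839). The mitotic kinase NEK2 differed by -0.71 (SE 0.12), the spindle protein NUSAP1 by -0.55 (SE 0.11), the centromeric histone CENPA by -0.45 (SE 0.08) and the kinase AURKB by -0.39 (SE 0.08). Of its members 13 were lower at an unadjusted p under 0.05, 4 adjusted over the list alone, and 0 over all genes.

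Both calls rest on camera's preset correlation of 0.01 between members. By fry the unadjusted p was 0.031 for DNA replication and 0.030 for mitosis, and the adjusted p was 0.356 for each. On simulated data of this design, a real list shift of -0.30 was called with the preset correlation and missed with the estimated one. The simulated genes were uncorrelated, so this does not speak to false calls among correlated members. In the data the estimated correlation was 0.32 for DNA replication and 0.14 for mitosis. Set against wild-type replicate 2 alone, the DNA replication list had a median of -0.31 and 27 of 30 members lay below that array in both H1069Q arrays; for mitosis these values were -0.17 and 27 of 32. The actin 3' minus 5' gap was larger by 0.22 in H1069Q arrays, where both lists were lower. Within the wild-type pair that gap was larger in replicate 1 (1.12 against 1.07), yet both lists were higher there, by medians of 0.20 and 0.12. The GAPDH gap was ordered the other way in that pair (0.24 in replicate 1 and 0.28 in replicate 2).

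Targets of p53, the stress-activated transcription factor, were higher in H1069Q cells, with positive differences in 16 of 19 members and a median of 0.26, and the list rose in the camera test with the preset correlation (adjusted p = 0.0123). The call was lost in camera with an estimated correlation, which was 0.63 for this list (unadjusted p = 0.416, adjusted p = 0.839). By fry the unadjusted p was 0.339. TP53I3 differed by 0.77 (SE 0.17), the cyclin-dependent kinase inhibitor CDKN1A by 0.58 (SE 0.13) and ZMAT3 by 0.46 (SE 0.15), whereas the DNA repair gene DDB2 differed by -0.32 (SE 0.09). At an unadjusted p under 0.05, 6 were higher and 2 lower; adjusted over the list alone 0 remained, and over all genes 0. Wild-type replicate 1 stood apart in this list: its median lay at -0.32 from the 4-array mean, against 0.05 in wild-type replicate 2 and 0.15 and 0.10 in the H1069Q arrays. Without it the call was lost (median 0.06, adjusted p = 0.275), as it was without probe sets marked as open to cross-hybridisation (adjusted p = 0.0550). The actin gap was larger in H1069Q arrays, where this list was higher. Within the wild-type pair that gap was 1.12 in replicate 1 and 1.07 in replicate 2, while the list was lower in replicate 1. The GAPDH gap was ordered the other way in that pair (0.24 in replicate 1 and 0.28 in replicate 2).

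Of the other 32 lists none passed. Without wild-type replicate 1, 11 of their medians were smaller by over 1.5 times and 5 larger by that factor. Of the 138 list members named in this text, 40 had smaller differences by over 1.5 times, 3 larger and 1 of opposite sign. The median of 8 lists turned sign or left 0 without that array: metallothioneins, TGF-beta targets, hepatocyte genes, oxidative phosphorylation, core histones, the p38 and JNK pathway, leukocyte markers and packaging cell genes. Leaving out wild-type replicate 2 did so for 3 (acute phase, NF-kB targets and fibroblast markers). Leaving out H1069Q replicate 1 did so for 4 (interferon response, autophagy, core histones and packaging cell genes), and H1069Q replicate 2 for 4 (the p38 and JNK pathway, autophagy, fibroblast and leukocyte markers). Nearest to passing was the lysosome, where 19 of 24 members were lower, with a median of -0.13 (camera adjusted p = 0.0693), which was -0.05 without wild-type replicate 1. The hydrolases GUSB (-0.65, SE 0.12), NEU1 (-0.45, SE 0.10) and GLA (-0.58, SE 0.13) were the 3 members lower when adjusted over the list alone, against 0 over all genes. The membrane protein LAMP1 differed by -0.39. Autophagy genes went both ways (15 higher and 16 lower of 31, adjusted p = 0.630), with SQSTM1 at 0.65, MAP1LC3B at 0.63, ATG7 at 0.31 and GABARAPL2 at -0.33; its median was -0.00 while its mean was 0.02.

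Because the H1069Q protein is held back in the ER, lists of ER stress and protein quality control were of interest. ER chaperones had a median of 0.02 (12 of 23 higher, adjusted p = 0.539), with DNAJC10 at 0.49, SEC61B at 0.29, CALR at -0.32 and WFS1 at -0.36. ER-associated degradation had a median of 0.11 (13 of 20 higher, adjusted p = 0.188), led by UBE2J1 (0.73), DERL2 (0.51), EDEM3 (0.42) and UBE2G2 (0.34). That median was 0.04 without wild-type replicate 1, and UBE2J1 then differed by 0.37. The ATF4 and CHOP response had a median of 0.06 (17 of 25 higher, 6 at an unadjusted p under 0.05, adjusted p = 0.108), with WARS1 at 0.70, PPP1R15A at 0.62, SLC3A2 at 0.57 and CTH at 0.57. Cytosolic heat shock genes had a median of 0.11 (13 of 17 higher, adjusted p = 0.191), with HSPH1 at 0.55, CHORDC1 at 0.41, DNAJA1 at 0.36 and HSPB1 at -0.28. With wild-type replicate 1 left out that median was 0.05, HSPH1 0.20, CHORDC1 0.12 and DNAJA1 0.09. Proteasome subunits had a median of 0.00 (0.02 without that array, 16 of 28 higher, adjusted p = 0.351), with PSMC4 at 0.43, ADRM1 at 0.28, PSMA5 at 0.24 and PSMD12 at 0.26. ER to Golgi transport had a median of 0.09 (0.04 without that array, 20 of 30 higher, adjusted p = 0.152), with the coat subunits COPG1 at 0.43 and ARCN1 at 0.27, STX5 at 0.32 and KDELR3 at -0.49. In these 6 lists 0 members were called, adjusted over the list alone or over all genes.

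The p38 and JNK pathways are stress kinase cascades that have been tied to the fate of the H1069Q protein. Their 37 measured members were split, 20 higher and 17 lower, with a median of 0.01 and a camera adjusted p of 0.953 in the downward direction. MAP2K6, an activator of p38, differed by -0.60 (SE 0.11), MAPK13, a p38 isoform, by 0.64 (SE 0.21; 0.33 without wild-type replicate 1), HSPB1 by -0.28 and JUND by -0.34. Transcript levels do not report kinase activity. Immediate early and ERK feedback genes had a median of 0.21 (0.09 without that array, 17 of 28 higher, 8 at an unadjusted p under 0.05, adjusted p = 0.113), with FOSL1 at 0.72, KLF10 at 0.54, SPRY4 at 0.47 and EGR1 at 0.42. In both lists 0 members were called, adjusted over the list alone or over all genes.

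Copper handling genes had a median of -0.05 (-0.09 without wild-type replicate 1, 11 of 19 lower, adjusted p = 0.430). LOX, a copper-dependent oxidase of the extracellular matrix, read 10.15 ± 0.21 in wild-type and 9.46 ± 0.10 in H1069Q arrays (-0.69, SE 0.13) and was the 1 member called adjusted over the list alone, against 0 over all genes. ATOX1, the chaperone that hands copper to ATP7B, differed by -0.60 (SE 0.18; -0.34 without that array), ceruloplasmin (CP) by -0.38 and PRNP by 0.41. Metallothioneins, metal-binding proteins induced by copper and zinc, had a median of -0.18 (6 of 8 lower, adjusted p = 0.630) that was 0.03 without wild-type replicate 1, when 5 of 8 lay above wild-type replicate 2 in both H1069Q arrays. Single values were MT1F at -0.28, MT1X at -0.18, MT1H at -0.18 and MT3 at 0.39. These genes are near-identical and their probe sets can cross-hybridise, so single members are uncertain. NRF2 antioxidant genes had a median of -0.05 (12 of 19 lower, adjusted p = 0.630), with HMOX1 at 0.44, ABCC3 at 0.41, PIR at -0.45 and GSR at -0.30. In the last 2 lists 0 members were called, adjusted over the list alone or over all genes.

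In lipid and energy metabolism, cholesterol synthesis genes had a median of 0.10 (11 of 17 higher, adjusted p = 0.188), with HMGCS1 at 0.56, SC5D at 0.35, IDI1 at 0.31 and EBP at -0.31. Fatty acid synthesis had a median of -0.06 (-0.04 without wild-type replicate 1, 9 of 14 lower, adjusted p = 0.630), with LPIN1 at 0.28, ACACA at 0.14, ACACB at -0.31 and ELOVL5 at -0.19; the probe sets of ELOVL5 disagreed in sign. Fatty acid oxidation had a median of -0.16 (12 of 18 lower, 6 at an unadjusted p under 0.05, adjusted p = 0.156), with ANGPTL4 at -0.48, HADH at -0.45, ACAA2 at -0.25 and SLC25A20 at -0.24. Without wild-type replicate 1 this median was -0.08, with 8 members below and 8 above wild-type replicate 2 in both H1069Q arrays. Glycolysis and hypoxia targets had a median of -0.12 (21 of 28 lower, adjusted p = 0.107), with the glucose transporter SLC2A3 at -0.98, P4HA1 at -0.77, PFKL at -0.33 and HK2 at 0.28. Oxidative phosphorylation had a median of -0.03 (0.00 without that array, 22 of 33 lower, adjusted p = 0.630), with ATP5F1C at -0.22, COX8A at -0.19, NDUFC1 at 0.20 and SDHD at 0.16. In these 5 lists 0 members were called, adjusted over the list alone or over all genes.

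Hepatocyte secreted and identity genes had a median of -0.05 (0.00 without wild-type replicate 1, 21 of 31 lower, adjusted p = 0.630). TAT, which degrades tyrosine, was the 1 member called adjusted over the list alone (0.51, SE 0.08), against 0 over all genes. FGB differed by 0.29, F10 by -0.29 and APOC3 by -0.54. Drug and bile acid metabolism had a median of -0.21 (8 of 10 lower, adjusted p = 0.156, 0 adjusted over the list alone and 0 over all genes), with CYP1A1 at -0.90, ABCB4 at -0.29, CYP27A1 at -0.22 and ABCB1 at 0.28. This median was -0.10 without wild-type replicate 1, and CYP1A1 then differed by -0.48. Acute phase genes had a median of 0.03 (0.12 without that array and -0.03 without wild-type replicate 2, 8 of 15 higher, adjusted p = 0.430). Adjusted over the list alone, IL6R was higher (0.52, SE 0.10) and HAMP lower, against 0 over all genes, while FGB and ORM1 (0.40) were higher without passing.

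Interferon response genes had a median of -0.05 (0.01 without H1069Q replicate 1, 14 of 21 lower, adjusted p = 0.430). Adjusted over the list alone 3 were lower, against 0 over all genes: PSMB9, an immunoproteasome subunit, IFI6 (-0.74, SE 0.14) and ISG15 (9.72 ± 0.07 against 9.02 ± 0.09, difference -0.70, SE 0.09). MX2 differed by 0.27. NF-kB targets were evenly split (8 of 16 higher, median -0.04, -0.09 without wild-type replicate 1 and 0.02 without replicate 2, adjusted p = 0.789). Adjusted over the list alone, TNFAIP3 (-0.73, SE 0.17), ICAM1 (-0.41) and CCL20 (-0.33) were lower and IL32 (0.39) higher, against 0 over all genes. Apoptosis regulators had a median of 0.15 (16 of 26 higher, adjusted p = 0.430, 0 adjusted over the list alone and 0 over all genes), with XIAP at 0.80, BCL2L1 at 0.31, BIRC2 at -0.28 and BIRC5 at -0.29. Without wild-type replicate 1 this median was 0.08 and XIAP differed by 0.39. The XIAP probe set was dim in wild-type arrays (mean 4.98), and another XIAP probe set differed by 0.17.

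Core histone genes were split 5 and 5 (median 0.03, -0.02 without wild-type replicate 1, adjusted p = 0.496). H2BC21 (6.59 ± 0.00 against 7.25 ± 0.01, difference 0.66, SE 0.08) and H2AC6 were higher adjusted over the list alone, against 0 over all genes, while H2BC9 was at -0.33 and H2AC8 at -0.24; histone genes are near-identical, so single members are uncertain. Cytosolic ribosomal proteins had a median of -0.02 (21 of 30 lower, adjusted p = 0.630, 0 adjusted over the list alone and 0 over all genes), with RPL22 at -0.20, RPS15 at -0.14, RPS9 at -0.11 and RPL11 at -0.10; the probe sets of RPL22 disagreed in sign. TGF-beta targets and matrix genes had a median of -0.12 (13 of 18 lower, adjusted p = 0.191), which was 0.02 without wild-type replicate 1, with 8 members below and 8 above wild-type replicate 2 in both H1069Q arrays. ID3, an inhibitor of differentiation factors, differed by -1.01 (SE 0.20) and the growth factor BMP4 by -0.58 (SE 0.13), and both were lower adjusted over the list alone, against 0 over all genes. ID1 differed by -0.51 and ACTA2 by 0.49.

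Lists of other cell types were included because a culture can hold other cells and virus stocks carry RNA of the packaging line. The filter on dim probe sets removed 8 of 15 fibroblast, 6 of 13 endothelial and 5 of 16 leukocyte markers. It also removed 1 of 12 cholangiocyte markers and 7 of 14 packaging cell genes. Some members named here lay near the cut, such as TEK (5.35 in wild-type arrays) and CDH5 (5.47 in H1069Q arrays). Others, such as EPCAM (12.28 in wild-type arrays), did not. Fibroblast and stellate cell markers had a median of 0.01 while the camera test pointed down (adjusted p = 0.642). FBLN1 (-0.42) was the 1 member called adjusted over the list alone, against 0 over all genes, but its probe sets disagreed in sign; RGS5 was at -0.08, COL1A2 at 0.12 and PDGFRB at -0.15. Endothelial markers had a median of -0.06 (adjusted p = 0.630), with CDH5 at -0.44, TEK at 0.26, CLDN5 at -0.16 and ENG, whose probe sets disagreed in sign, at -0.10. Leukocyte markers had a median of -0.01 (adjusted p = 0.630), with CD3D at -0.61, LCP1 at -0.23, CD14 at -0.12 and ITGAM at 0.18. Cholangiocyte and progenitor markers had a median of -0.11 (adjusted p = 0.630), with PROM1 at -0.54, EPCAM at 0.26, SPP1 at -0.17 and CD24, whose probe sets disagreed in sign, at -0.24. Packaging cell genes had a median of 0 and a mean of -0.01 (adjusted p = 0.953), with INA at 0.26, TUBB3 at -0.13, UCHL1 at 0.06 and PAX8, whose probe sets disagreed in sign, at -0.25. Without wild-type replicate 1 the medians of these 5 lists were 0.03, -0.03, 0.04, -0.03 and -0.01 in the order given. In the last 4 lists 0 members were called, adjusted over the list alone or over all genes.

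**Figure D2:**
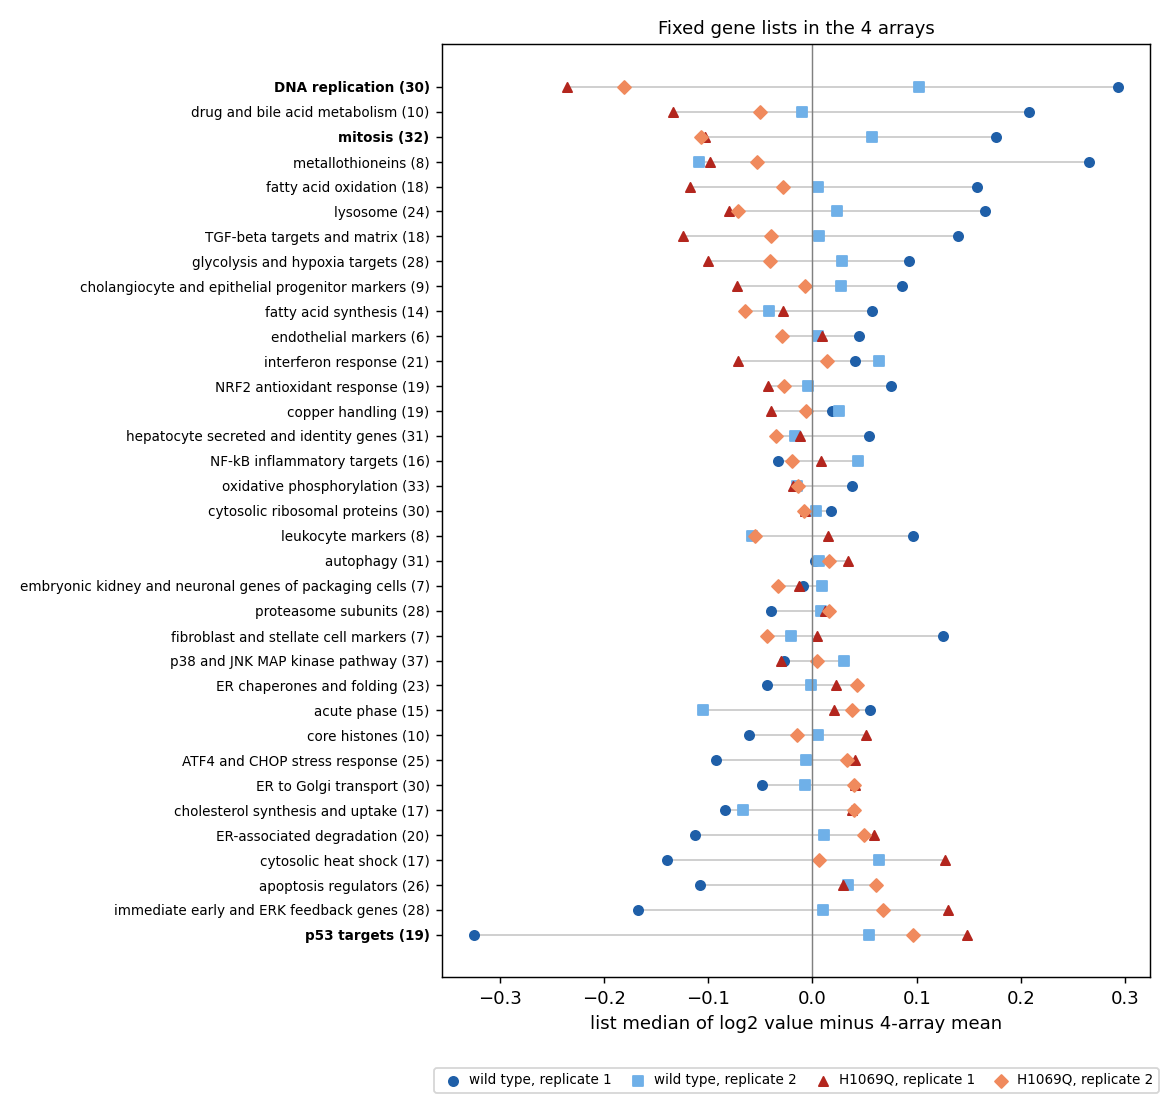
Median over each list's measured genes of the log2 value minus the gene's 4-array mean (horizontal axis), with 1 symbol per array, for the 35 lists; parentheses give the genes measured and bold names mark camera adjusted p under 0.05. In DNA replication the H1069Q arrays lie at -0.24 and -0.18 and the wild-type arrays at 0.29 and 0.10, whereas in p53 targets wild-type replicate 1 lies at -0.32 and the other arrays between 0.05 and 0.15.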

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

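The tests of wild-type replicate 1 as the sole source, and of larger noise in that array, were chosen after the result was seen; the tests of RNA quality, of equal noise, of dim probe sets and of other splits were written before. Each group had 2 arrays, too few for a test of outlying arrays, and 1 contrast leaves no difference between contrasts to test.

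Control probe sets outside the gene comparison carried a difference between the groups. The actin 3' minus 5' gap was larger by 0.22 in H1069Q arrays, and the GAPDH gap by 0.0646, above the wild-type level in both arrays. 18S rRNA (0.04) overlapped between the groups. Hybridization spikes were higher by 0.06 and poly-A spikes differed by -0.05, both without overlap. Of 1860 probe sets that name several genes or none, 71 had an unadjusted p under 0.01 with no overlap of arrays, 30 higher and 41 lower. At that p 19 would be expected if none differed, without allowing for probe sets that vary together.

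The lower values of DNA replication genes in H1069Q cells were weighed first. Wild-type replicate 1 as the sole source was argued against: set against wild-type replicate 2 alone, the median over these genes was still -0.31. That is farther from 0 than the median of 0.20 between the wild-type arrays (replicate 1 minus 2) and the median absolute difference of 0.08 between the H1069Q arrays, but it rests on 1 wild-type array, and a part from replicate 1 remains possible. RNA quality stays open. If it scaled with the actin gap, H1069Q replicate 1 minus replicate 2 would have had a median of -0.23 over these genes. The measured value was -0.0325 (95% interval over resampled genes -0.08 to -0.01), of the predicted sign but smaller. That interval treats the genes as independent and does not measure the spread between arrays, so it is too narrow. In the wild-type pair the actin gap was larger in replicate 1 (1.12 against 1.07), where these genes were higher by a median of 0.20, opposite to that scaling. The GAPDH gap was smaller in that array (0.24 against 0.28), so a partial contribution cannot be told apart. A difference in transgene dose or virus load, and the H1069Q variant itself, may also underlie the pattern and were not tested.

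The position of wild-type replicate 1 was the next pattern. Independent noise of equal size in the 4 arrays was argued against: across genes, which are not independent replicates, wild-type replicate 1 minus replicate 2 correlated with H1069Q minus wild type at -0.66, where equal noise gives about 0. Dim probe sets were argued against as the source, since over the brighter genes the correlation was -0.80. Larger noise in wild-type replicate 1 alone could also give a negative value. The within-group differences, which share no array, correlated at -0.26, between the bounds set for deciding. H1069Q replicate 1 minus replicate 2 correlated with H1069Q minus wild type at 0.35, where noise in wild-type replicate 1 alone gives about 0. No bound was set beforehand for this value, which argues against that noise as the only source. A part from that noise cannot be told apart from a graded state of the cultures. In such a state wild-type replicate 2 lies between replicate 1 and the H1069Q arrays. It lay between replicate 1 and the H1069Q mean in 53.5% of genes. No reference share was computed, so this value does not decide between noise and a graded state.

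The 2041 genes at an unadjusted p under 0.05 in limma came from 1 of the 3 ways to split the 4 arrays into 2 and 2. The highest count of the other splits was 68. In those splits the difference between the groups enters the residual spread and lowers the counts, here under the 458 expected if none differed. They are therefore no reference for what chance would give. With 3 splits the share cannot fall under 0.05.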

How the results depend on the processing

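The crossed pairing and the removal of cross-hybridising probe sets were chosen after the data were seen. The count of 0 genes past adjusted p 0.05 with limma held in every alternative except leaving out wild-type replicate 2, so leaving out 1 array gave 0 to 1647. Genes at an unadjusted p under 0.05 numbered 3085 over every probe set, where more features were tested, and 585 (without H1069Q replicate 1) to 3467 (without wild-type replicate 2) when 1 array was left out, with 1018 without H1069Q replicate 2. The 3 shifted lists became 6 with the mean of probe sets, 0 with an estimated correlation, 0 by fry, and 2 (without wild-type replicate 1) to 9 (without wild-type replicate 2) when 1 array was left out, with 7 without H1069Q replicate 2. By construction the estimated correlation and fry left the medians at -0.43 for DNA replication, -0.20 for mitosis and 0.26 for p53 targets but ended all 3 calls; without cross-hybridising probe sets the p53 median was again 0.26 and its call ended. The p53 median ranged from 0.0592 without wild-type replicate 1, which ended the call, to 0.476 without wild-type replicate 2. Apart from the estimated correlation, fry and these array effects, the cause of each shift was not tested. With the replicate block, 0 genes passed, 1453 had an unadjusted p under 0.05 and 3 lists shifted. Deviations of same-numbered arrays correlated at -0.26, which gives no ground to pair samples by number. This value could also come from crossed numbers or from a graded state of the cultures. A crossed pairing gave 0 genes, 2417 at an unadjusted p under 0.05 and 8 lists. The ATP7B difference stayed negative and uncalled, from -0.25 to -0.08 when 1 array was left out. Over 159 named genes, 2253 of 2352 alternative results stayed uncalled. The rest all came from leaving out wild-type replicate 2, a fit with 1 wild-type array. Over 35 lists, 559 of 590 stayed on their side of the threshold, 8 lost a call and 23 gained one, 8 of them for the lysosome. The other gains were for the ATF4 and CHOP response, immediate early genes, glycolysis and hypoxia, cytosolic heat shock, drug and bile acid metabolism and fatty acid oxidation. Across genes and lists 0 results reversed, and 6 uncalled gene differences and 30 uncalled list medians changed sign. Low signal over background limits dim genes, and the RMA background step could not be redone. The choice of probe set also matters for some list members named in Results. Another probe set lay near 0 for JUND (-0.0027), ICAM1 (-0.03), BIRC5 (-0.03), HK2 (0.01), EDEM3 (0.06) and LPIN1 (0.02).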

Other observations

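The tests of the methionine cycle, BMP target and EGF receptor ligand lists were all chosen after the gene values were seen, and the BMP values restricted to members not named elsewhere were added once the whole list had been tested.

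Some of the largest differences fell outside the naming rule because their p was over 0.01, and these genes were chosen after their values were seen. EREG, a ligand of the EGF receptor, read 5.74 ± 1.25 in wild-type and 7.59 ± 0.19 in H1069Q arrays (1.84, SE 0.55), the water and glycerol channel AQP3 differed by 1.68 (SE 0.53) and AGR2 by 1.53 (SE 0.41). TXNIP, a glucose-responsive regulator of thioredoxin, read 8.39 ± 1.33 and 6.62 ± 0.14 (-1.77, SE 0.58). All 4 had adjusted p over 0.05 in limma and a wide spread between the wild-type arrays. A list of 8 measured EGF receptor ligand and AP-1 genes was split, 4 higher (among them FOSL1 at 0.72 and SPRY4 at 0.47) and 4 lower (among them TGFA at -0.22 and PLAUR, whose probe sets disagreed in sign, at -0.25), and gave a camera p of 0.362. Without wild-type replicate 1 these differences were smaller: 0.96 for EREG, 0.82 for AQP3, 0.88 for AGR2 and -0.83 for TXNIP.

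Enzymes of the methionine cycle differed in opposite directions. MAT2A, the S-adenosylmethionine synthetase of proliferating and extrahepatic cells, was at 1.55 (SE 0.44), whereas MAT1A, the form of adult liver, was at -0.39 (SE 0.12). The liver enzymes BHMT and GNMT, which remethylate homocysteine and consume S-adenosylmethionine, were at -1.27 (SE 0.34) and -0.69 (SE 0.20), and CTH and SRM at 0.57 and 0.53. None passed adjustment, and without wild-type replicate 1 the differences were smaller: 0.86 for MAT2A, -0.25 for MAT1A, -0.74 for BHMT, -0.39 for GNMT, 0.36 for CTH and 0.37 for SRM. A shift of this list as a whole was not found over 20 measured genes (unadjusted p of 0.574 by limma's camera), which decides little for members that go both ways.

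HAMP, ID1 and ID3 belong to genes induced by BMP signalling through SMAD1 and SMAD5, and BMP4 is a ligand of that pathway. A candidate hypothesis is that this signalling was lower in H1069Q cells. The list tested mixes such target genes with the ligands BMP4 and BMP6. Over the whole list, 11 of 12 measured genes were lower, with a median of -0.35 and a camera p of 9.02e-05 (0.162 with an estimated correlation), but that list holds the genes that prompted it and so decides nothing by itself. Over the 8 genes left without HAMP, ID1, ID3 and BMP4 the median was -0.21 (camera p of 0.0184, and 0.152 with an estimated correlation). Among them were the feedback inhibitors of the pathway SMAD7 at -0.52 and SMAD6 at -0.43 (-0.04 by another probe set). The whole list was already known to be lower when this was computed, so it adds no independent test and the hypothesis stays open. Several members also belong to the TGF-beta list, which did not pass, and 3 lists were tried in this way on the same arrays.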
